A study of Mus musculus with 16 samples.

How the data were processed

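PolyA RNA was sequenced from ventricular heart tissue of adult female mice of the inbred strains DBA/2J and C57Bl6/N, with 8 mice per strain, an age of 3 months and 1 library per mouse. In each strain 4 mice had permanent ligation of a coronary artery, which cuts off the blood supply of part of the left ventricle and causes an infarct, and 4 untreated mice were the controls. Tissue was taken 2 weeks after ligation. The labels' descriptions call the ligated samples remote, meaning tissue away from the infarct. The tissue is given in 2 ways, since the design text names the septum and the right ventricles while the label of every sample names the septum and the left ventricle, and the sources used here do not settle which is right. Libraries were made with the KAPA mRNA Hyperprep kit after extraction with RNeasy Plus Mini, per the labels' protocols.

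Reads were aligned to mm10 with STAR 2.5.2b and assigned to genes with featureCounts of Subread 1.5.1, and edgeR is named for the statistics, per the submitters' processing notes. The strand setting of the counting and the gene annotation are not given in the sources used here. Genes that overlap on opposite strands are therefore uncertain, as are genes with near-identical copies. DBA/2J reads were counted against a reference genome of C57BL/6 origin, so differences in sequence between the strains can lower DBA/2J counts.

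The authors deposited 1 table of whole-number read counts per gene and library, not normalized, per the file headers. The table holds 13842 genes, and the smallest total of a gene over the 16 libraries is 45 counts, so genes with fewer reads had been left out. The same deposited table gives the log2 fold changes of 5 comparisons made by the authors, per the file headers. The p-values and false discovery rates of those comparisons are also the authors', per the file headers. Gene coordinates on mm10 come from the same table. The other 16 per-sample columns of the table, which hold values on a normalized log scale, were not used here. Of the 4 DBA/2J ligated libraries, 3 columns carry mouse numbers that differ from the labels; these entered the group as replicates without a number and are named by their index S40, S41 and S42.

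Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by the filter of edgeR applied by group, which left 13504 genes. Library totals were scaled by the trimmed mean of M values (TMM). A negative binomial model with a mean for each of the 4 groups was fitted over all 16 libraries, so that the groups share 1 estimate of the spread, and the robust quasi-likelihood test was applied to 5 contrasts. The prior degrees of freedom were 5.45. The tests are two-sided, the p-values were adjusted by the Benjamini-Hochberg method within each contrast, and genes with an adjusted p under 0.05 are called. All adjusted p-values of genes come from this edgeR test unless another tool is named. Adjusted p-values are given beside log2 fold changes with their standard errors (SE), and levels are CPM, counts scaled to the TMM-adjusted library total, as mean ± SD over 4 mice. The 5 contrasts are ligation against control in each strain, the difference between these responses (the interaction, DBA/2J minus C57Bl6/N), and DBA/2J against C57Bl6/N in controls and in ligated mice.

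A total of 32 gene lists was tested, with 640 entries, of which 564 were among the tested genes. They cover cardiac stress, matrix, signalling, metabolism, immunity, the circadian clock, known differences between C57BL/6 and DBA/2 mice, and markers of cell types the tissue can hold. Each list was tested with camera of limma 3.58.1, a two-sided test of the list's genes against all other genes with a preset correlation of 0.01, adjusted by the Benjamini-Hochberg method over the 32 lists of a contrast. Camera was also run with a correlation estimated from the residuals, and fry tested whether a list's genes moved, on balance, one way. The contrasts, the tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined.

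Genes were named by a fixed rule. For the ligation contrasts and the control strain contrast these are, among called genes with a mean of at least 2 CPM in the higher group and 4 against 4 libraries that did not overlap, the 8 with the largest positive and the 8 with the largest negative log2 fold change, leaving out clone and model names. For the interaction and the contrast of ligated mice these are the 8 per direction with the smallest p among called genes under the same conditions on name and level. From each list described, up to 4 members with the smallest p are named, with any member needed to show both directions. All tested genes of the list of known strain differences are named in the strain contrasts, and a panel of 10 cardiac stress and matrix genes in the ligation contrasts and the interaction. A few genes outside this rule were chosen after their values were seen, which is said where they appear, and a few genes the rule names are not reported here.

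Library totals ran from 4.92 to 22 M counts (mega-counts). A floor of 3 counts, the limit that a count of 0 allows, corresponds to between 0.136 and 0.609 CPM in single libraries. Where a group had no count of a gene, the fold is given as a lower bound against 3 counts over the group; with 1 to 3 counts the ratio is given with its exact counting interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The smallest chi-square per degree of freedom between libraries of 1 group was 3.47, so no 2 libraries of a group agreed within sampling noise, and each was counted as a sample. The labels number the mice as separate biological replicates. They name C57 controls C57Bl-6NCR and ligated C57 mice C57Bl-6N. Any difference, not stated, would enter the C57 response.

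The alternatives were size factors by relative log expression, library totals without TMM, no filter on low counts, a filter of at least 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma's voom, a fit with only the groups compared, a block for the replicate number where columns carry one, other set tests, and leaving out each library in turn. After the data had been seen, 4 more were added. These were an offset for the trend of each library's counts with gene GC content (a spline with 5 degrees of freedom, centred so that it leaves the library's level unchanged, a step added after an uncentred form had shifted the balance of higher and lower calls), the fit without the 3 libraries under 9 M counts, both together, and the fit of the numbered libraries without a block. GC content was the mean over the gene's GENCODE M21 transcripts, matched by symbol for 13024 of the tested genes (96.4%).

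The fits were tested on counts simulated with the real libraries' means and sizes and known genes changed in the DBA/2J ligated group. For DBA/2J ligation against control, edgeR's test over 13365 genes recovered 38.8% of 67 genes changed 1.5-fold, 71.6% of 67 genes changed 2-fold and 98.5% of 66 genes changed 4-fold, with 6 false calls. For the interaction it recovered 11.9%, 52.2% and 97.0% of the same genes. C57Bl6/N, unchanged, had no false call. DESeq2, over 13504 genes, recovered 52.2%, 76.1% and 100% for DBA/2J ligation with 17 false calls, voom 37.3%, 71.6% and 100% with 6. When 1 list was raised 1.5-fold, camera called 1 of 32 lists, which does not test its preset correlation. A GC trend simulated in the DBA/2J controls gave 7298 edgeR calls, 0 with the GC offset. Real ones trended both ways, which was not tested.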

Results

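PolyA RNA was measured in ventricular tissue of 16 female mice, in 4 groups of 4. DBA/2J and C57Bl6/N mice (DBA and C57 in the following) were untreated or were examined 2 weeks after permanent coronary ligation. The design asks how each strain responds, whether responses differ and how strains differ with and without ligation. Untreated controls cannot tell infarct from surgery. Levels are CPM as mean ± SD with n = 4 mice per group. Adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (edgeR adjusted p), and those of gene lists from camera, adjusted in the same way over the 32 lists (camera adjusted p). Fold changes are on the log2 scale with their SE. For each gene named as called, the 4 libraries of 1 group lay beyond the 4 of the other group unless an overlap is stated.

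Library totals, in M counts (mega-counts), were 14, 17, 7.58 and 4.92 M in DBA controls 1 to 4, and 22, 15.1, 18.8 and 17.2 M in DBA ligated libraries 1, S40, S41 and S42. They were 8.22, 9.52, 14.2 and 12.2 M in C57 controls 1 to 4, and 20.9, 13.7, 15.3 and 15.4 M in C57 ligated libraries 1 to 4. Ligated libraries were deeper than control libraries, with 17.3 ± 3.00 against 11 ± 4.07 M (exact two-sided permutation test, p = 0.0042, 12870 arrangements). Within DBA the means were 18.3 ± 2.92 and 10.9 ± 5.59 M and within C57 16.3 ± 3.16 and 11 ± 2.70 M (exact two-sided permutation tests, p = 0.057 in each strain, where 70 arrangements allow no p under 0.029). The 50 most abundant genes held between 21.4% and 27% of the counts of a library, and no gene held more than 5.50%. The first principal component carried 44.7% of the variance and the second 25.3%.

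Libraries of 1 group stood apart from one another along gene GC content, most in the DBA controls. The deviations of a library's genes from their group means had a rank correlation with GC content of 0.46 and 0.51 in DBA controls 1 and 2 but of -0.30 and -0.48 in DBA controls 3 and 4. In C57 controls 1 to 4 it was -0.34, 0.02, 0.25 and 0.24, in the C57 ligated libraries it lay between -0.23 and 0.16 and in the DBA ligated libraries between -0.07 and 0.07. DBA controls 3 and 4 and C57 control 1 were the 3 libraries under 9 M counts, called the shallow libraries here. They were left out in an alternative chosen after this had been seen. These correlations are across genes, which are not independent replicates.

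**Figure D1:**
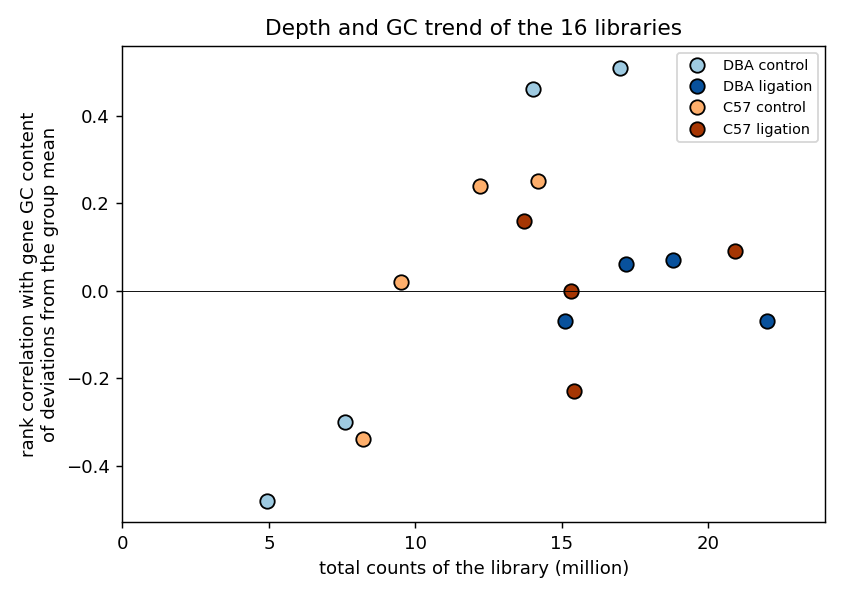
Each of the 16 points is a library, with its total counts in Ms on the x axis and, on the y axis, the rank correlation across genes between GC content and the deviation from the group mean. Colours mark the 4 groups, and the 3 libraries under 9 M counts lie at -0.30, -0.48 and -0.34.

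In DBA mice, ligation was followed by higher transcripts of the natriuretic peptides and of several matrix genes and by lower transcripts of several contractile, calcium-handling and fat-burning genes. Nppa, which encodes atrial natriuretic peptide (chromosome 4, 148000746 to 148002067 on mm10), was at 974 ± 134 CPM after ligation and at 359 ± 159 in controls. Myh6, the main myosin heavy chain of the adult mouse ventricle, was at 30607 ± 1106 and 49544 ± 8683 CPM. Nppb, the gene of brain natriuretic peptide, was at 161 ± 37.1 and 68.2 ± 36.0 CPM, and the fibrillar collagen gene Col3a1 at 2117 ± 279 and 1089 ± 197 CPM. The log2 fold change was 1.44 ± 0.25 for Nppa, -0.69 ± 0.12 for Myh6, 1.24 ± 0.30 for Nppb and 0.96 ± 0.20 for Col3a1 (edgeR adjusted p = 0.00282, 0.00277, 0.0105 and 0.00532). Acta1, the skeletal actin of the fetal heart, rose from 1539 ± 663 to 3477 ± 402 CPM and Col1a1 from 396 ± 62.0 to 739 ± 109.7. The matricellular Postn rose from 189.8 ± 67.7 to 417 ± 88.8 and the protease inhibitor Timp1 from 6.5 ± 1.53 to 11.7 ± 3.28. Their log2 fold changes were 1.18 ± 0.30, 0.90 ± 0.21, 1.15 ± 0.33 and 0.86 ± 0.27 (edgeR adjusted p = 0.0120, 0.00849, 0.0193 and 0.0295). The stretch-responsive Ankrd1 was higher by 0.64 ± 0.21 in libraries that overlapped (2438 ± 910.0 and 3794 ± 275 CPM, edgeR adjusted p = 0.0356). Myh7, the fetal myosin heavy chain, was at 2609 ± 693 CPM in controls and 2001 ± 113 after ligation and was not called (-0.38 ± 0.29, edgeR adjusted p = 0.331).

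Of this panel, Nppa and Myh6 were called in DBA under each alternative. Without the shallow libraries, the edgeR adjusted p was 0.148 for Nppb, 0.238 for Acta1, 0.0788 for Col1a1, 0.0518 for Col3a1, 0.101 for Postn and 0.134 for Timp1. Over all alternatives it ran from 0.000929 to 0.148, 0.00125 to 0.291, 0.000724 to 0.117, 0.000127 to 0.0519, 0.0110 to 0.101 and 0.0167 to 0.139 for these genes, and from 0.00598 to 0.0872 for Ankrd1. Leaving out 1 library ended the call of Acta1 without DBA control 3 (edgeR adjusted p = 0.050), of Postn without DBA control 3 (0.0636) or DBA ligated S41 (0.0612), and of Timp1 without DBA control 1 (0.0856), DBA control 3 (0.0629), DBA ligated 1 (0.0578) or S41 (0.101). Ankrd1 lost its call without DBA control 1 (0.0872), 2 (0.0577) or 3 (0.0865), or without DBA ligated S40 (0.0646), S41 (0.0700) or S42 (0.0772).

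**Figure D2:**
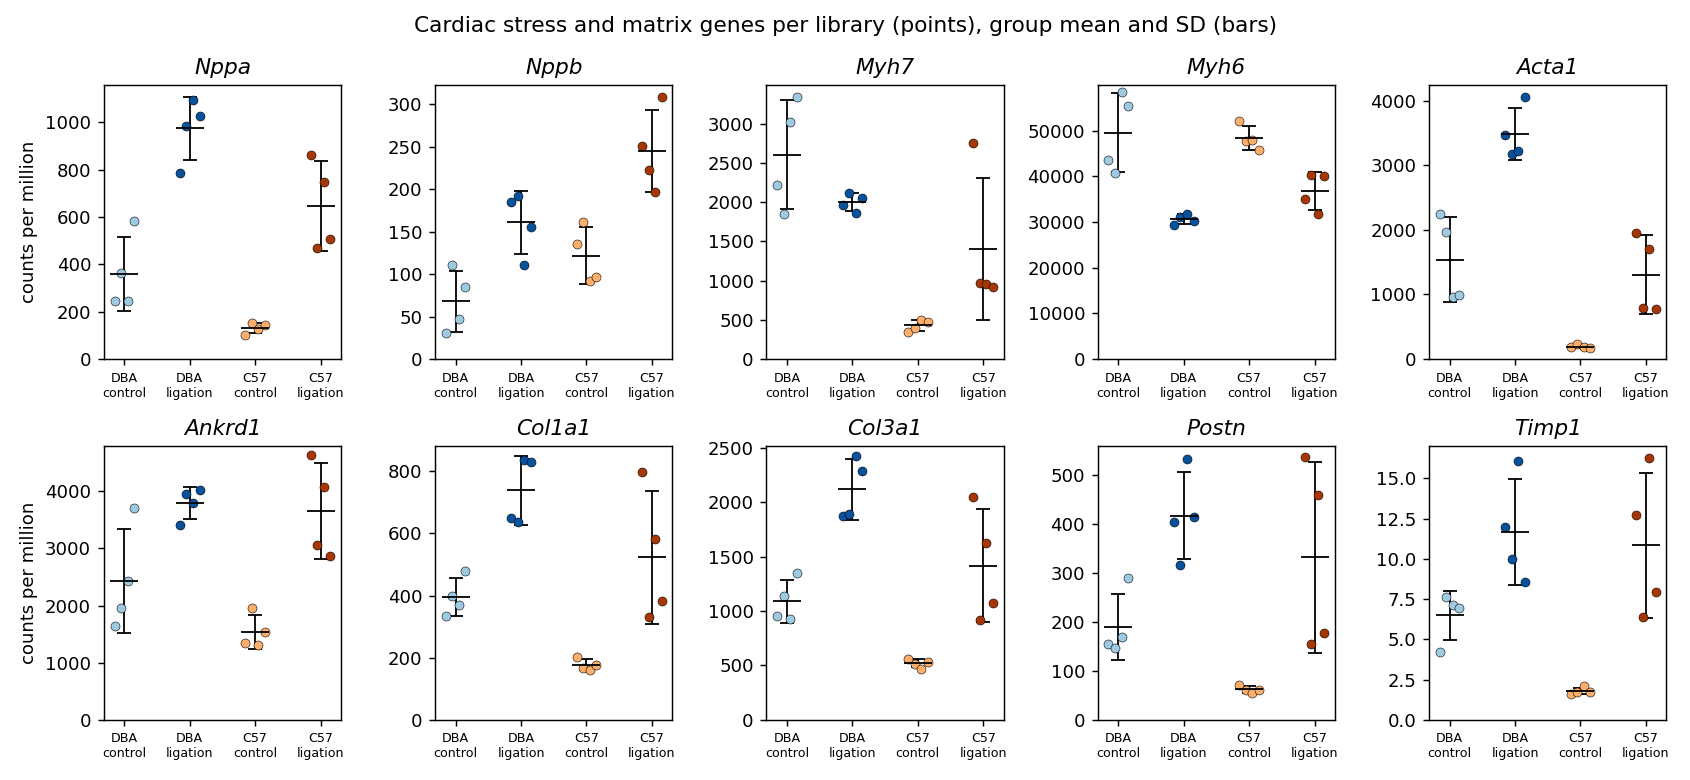
CPM of the 10 panel genes, 1 panel per gene with its own y axis, in the 4 groups on the x axis. Points are libraries and bars the mean with SD over 4 mice. Mean Myh7 rises from 428 to 1401 CPM in C57 (2759.8 in ligated 1) and is 2609 and 2001 in DBA.

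The 8 genes with the largest rise in DBA hearts included Adamtsl2, a secreted matrix glycoprotein of the ADAMTS-like family, at 12.2 ± 5.15 CPM in controls and 39.9 ± 4.54 after ligation. They also included the stress-induced cytokine Gdf15, at 0.932 ± 0.615 and 3.38 ± 0.449 CPM. The cartilage collagen Col9a2 rose by 2.25 ± 0.50, the calcium-dependent kinase Camk1g by 1.94 ± 0.41, the mitotic spindle protein Spag5 by 1.83 ± 0.41 and Fam46b by 1.70 ± 0.44. Iqgap3 rose by 1.64 ± 0.41, the matrilin Matn4 by 1.64 ± 0.37, Adamtsl2 by 1.62 ± 0.28 and Gdf15 by 1.62 ± 0.36 (edgeR adjusted p from 0.00282 to 0.0131 over these 8 genes). The 8 genes with the largest fall included the kinase Sbk3, at 21.2 ± 16.2 and 3.07 ± 1.15 CPM. Lrrc10b was at 2.93 ± 0.954 and 0.673 ± 0.342 CPM and Cyp26b1, an enzyme that degrades retinoic acid, at 11.6 ± 5.46 and 2.94 ± 1.10. Their log2 fold changes were -2.68 ± 0.46, -2.18 ± 0.35 and -1.97 ± 0.43 (edgeR adjusted p = 0.00278, 0.00257 and 0.00666). The atrial genes Sln (-2.61 ± 0.87), Myl7 (-2.50 ± 0.76) and Mybphl (-2.24 ± 0.74), the lectin gene Clec3a (-2.57 ± 0.68) and Hamp, which encodes the iron hormone hepcidin and has the near-identical copy Hamp2 (-2.07 ± 0.49), also fell (edgeR adjusted p = 0.0369, 0.0257, 0.0360, 0.0139 and 0.00954). Camk1g, Spag5, Sbk3, Lrrc10b and Cyp26b1 were called under each alternative.

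Sln, Myl7 and Mybphl, markers of atrial muscle, were called close to the threshold. Over the alternatives the edgeR adjusted p ran from 0.0206 to 0.238, 0.0136 to 0.192 and 0.0246 to 0.166, with the call of each lost without the shallow libraries (folds then -2.438, -2.435 and -2.212, from fewer libraries). It was also lost without DBA control 1 (edgeR adjusted p = 0.0841, 0.0553 and 0.0872), control 3 (0.0646, 0.0504 and 0.0512), control 4 (0.108, 0.0948 and 0.0921), DBA ligated 1 (0.0847, 0.0683 and 0.0873), S41 (0.0908, 0.0630 and 0.0912) or S42 (0.0879, 0.0692 and 0.0856), though no single library moved a fold of these 3 by over 1.5 times. For Col9a2, Fam46b, Iqgap3, Adamtsl2, Clec3a and Hamp the call ended without the shallow libraries (edgeR adjusted p = 0.0709, 0.0508, 0.0623, 0.0626, 0.0659 and 0.0896), and for Matn4 and Gdf15 when the GC offset was applied as well (0.0553 and 0.0596). The fold of Gdf15 was 2.22 without DBA control 2, of Sbk3 -2.09 without DBA control 4 and of Clec3a -3.76 without DBA ligated S41.

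Matrix genes rose together in DBA hearts. Of 47 tested collagens and matrix genes, 36 were called higher, 0 lower and 11 not called, and 37 higher and 0 lower when adjusted over the list alone, with a median log2 fold change of 0.90 (camera adjusted p = 1.66e-13; adjusted p = 0.39 with an estimated correlation). The gelatinase Mmp2 rose by 0.96 ± 0.13, the membrane protease Mmp14 by 1.13 ± 0.16, the basement membrane collagen Col4a1 by 1.25 ± 0.21 and the collagen-binding Sparc by 0.93 ± 0.15 (edgeR adjusted p from 0.00183 to 0.00270). Without the shallow libraries 7 matrix genes were called higher and 0 lower by edgeR, with a median of 0.88. Of 24 TGF-beta and myofibroblast genes 8 were called higher, among them the ligand Tgfb3 (0.59 ± 0.10) and the matricellular Ctgf (0.96 ± 0.18), and 0 lower, with 9 and 1 adjusted over the list alone. The list's median was 0.22 (camera adjusted p = 0.0314; adjusted p = 0.45 with an estimated correlation), and the camera adjusted p was 0.106 without DBA control 1, 0.0824 without DBA control 2 and 0.0515 without DBA ligated S41. Of 16 fibroblast markers 8 were higher, also when adjusted over the list alone, and 0 lower. Their median was 0.40 (camera adjusted p = 0.00124; adjusted p = 0.39 with an estimated correlation). Of 19 stress and fetal cardiomyocyte genes 9 were higher and 0 lower, 10 and 0 adjusted over the list alone. Their median was 0.36 (camera adjusted p = 0.00557; adjusted p = 0.39 with an estimated correlation, and 0.0507 with the GC offset).

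Fatty acid oxidation, oxidative phosphorylation, calcium handling and sarcomere genes were lower as lists. Of 30 fatty acid oxidation genes 16 were called lower and 0 higher, 18 and 0 adjusted over the list alone. Their median was -0.40 (camera adjusted p = 4.02e-06; adjusted p = 0.39 with an estimated correlation); the lipoprotein lipase gene Lpl was at -0.78 ± 0.13 and the mitochondrial reductase gene Decr1 at -0.61 ± 0.10 (edgeR adjusted p = 0.00270 for each). Of 60 genes of oxidative phosphorylation and the TCA cycle 20 were lower and 0 higher, 24 and 0 adjusted over the list alone. Their median was -0.19 (camera adjusted p = 0.000562; adjusted p = 0.45 with an estimated correlation). Of 30 genes of calcium handling and ion channels 17 were lower and 0 higher, 17 lower and 1 higher adjusted over the list alone. Their median was -0.40 (camera adjusted p = 0.000182; adjusted p = 0.39 with an estimated correlation). The inward rectifier channel Kcnj2 was at -1.01 ± 0.17 and Hrc, a calcium-binding protein of the sarcoplasmic reticulum, at -1.11 ± 0.19 (edgeR adjusted p = 0.00277 and 0.00309). Of 20 adult sarcomere genes 10 were lower, among them Myh6 and the ventricular light chain Myl2 (-0.63 ± 0.12, edgeR adjusted p = 0.00406), and 1 was higher, Mybpc3 (0.51 ± 0.11, edgeR adjusted p = 0.00651, and from 0.000180 to 0.0519 over the alternatives). The counts were the same adjusted over the list alone, the median was -0.34, and the camera adjusted p was 0.00140 (adjusted p = 0.39 with an estimated correlation). Glycolysis had 4 genes higher and 1 lower of 20, 6 and 1 adjusted over the list alone. Their median was 0.06 (camera adjusted p = 0.545). Of 9 atrial markers 1, Nppa, was higher and 4 were lower, 1 and 6 adjusted over the list alone. Their median was -1.30 (camera adjusted p = 0.157, and 0.0380 with the GC offset); the channel gene Kcnj3 was at -1.30 ± 0.17 (edgeR adjusted p = 0.00183).

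Several genes of dividing cells, interferon response, complement, macrophages and endothelium were higher in DBA hearts after ligation. Of 30 cell cycle genes 12 were called higher and 0 lower, 15 and 0 adjusted over the list alone. Their median was 0.80 (camera adjusted p = 4.53e-05; adjusted p = 0.45 with an estimated correlation). Of 29 interferon response genes 12 were higher and 0 lower, by either adjustment. Their median was 0.49 (camera adjusted p = 0.000182; adjusted p = 0.45 with an estimated correlation). The antiviral genes Rsad2 and Oas1a rose by 0.84 ± 0.20 and 0.97 ± 0.24 and the signal transducer Stat2 by 0.49 ± 0.11 (edgeR adjusted p = 0.00977, 0.0104 and 0.00637). Of 16 complement genes 7 were higher and 0 lower, 9 and 0 adjusted over the list alone. Their median was 0.34 (camera adjusted p = 0.00698; adjusted p = 0.39 with an estimated correlation). They included C4b at 1.22 ± 0.20 and Cfb at 1.20 ± 0.25 (edgeR adjusted p = 0.00270 and 0.00532). Of 24 macrophage markers 11 were higher and 0 lower, 12 and 1 adjusted over the list alone. Their median was 0.48 (camera adjusted p = 0.00698; adjusted p = 0.45 with an estimated correlation). Of 16 endothelial markers 8 were higher and 0 lower, 11 and 1 adjusted over the list alone. Their median was 0.36 (camera adjusted p = 0.00160; adjusted p = 0.39 with an estimated correlation).

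Adipocyte markers were the remaining list called in DBA by camera, with 1 gene lower and 0 higher of 6, by either adjustment, a median of -1.04 and a camera adjusted p of 0.0364 (adjusted p = 0.45 with an estimated correlation). That call ended without the shallow libraries (camera adjusted p = 0.0596), DBA control 1 (0.0657), DBA control 2 (0.0824) or DBA ligated S41 (0.0650). MHC class II genes had 0 genes called of 11 by edgeR, by either adjustment, and a median of 0.40 (camera adjusted p = 0.0761, and 0.0437 without the shallow libraries or 0.0182 without DBA control 3). The other lists were not called by camera. Pericyte and smooth muscle markers had 5 higher and 1 lower of 12, 7 and 2 adjusted over the list alone. Their median was 0.26 (camera adjusted p = 0.189). Of 18 clock genes 1 was higher and 5 lower by either adjustment (-0.15, 0.211), where the values in brackets are the median and the camera adjusted p. Of 15 hypoxia genes 1 was higher and 4 lower by either adjustment (-0.11, 0.138), and of 18 genes of the unfolded protein response 2 and 3 by either adjustment (0.08, 0.831). Of 21 cytokines 1 was higher and 1 lower, 1 and 0 adjusted over the list alone (0.13, 0.831). Immediate early genes had 2 higher and 1 lower of 20 (-0.04, 0.975), glucocorticoid genes 0 and 1 of 12 (0.24 with a mean of 0.02, 0.975), both with 0 adjusted over the list alone. Epicardial markers had 1 and 0 of 6 (0.99, 0.174) and known strain genes 1 and 0 of 12 (0.10, 0.465), both the same adjusted over the list alone. No gene was called by edgeR among 3 neutrophil markers (-0.16 against a positive test, 0.989), 4 T and NK cell markers (-0.16 against a positive test, 0.975) or 4 B cell markers (-0.39, 0.431), nor among 3 erythroid markers (0.76, 0.545), 6 Schwann cell markers (0.06 against a negative test, 0.989) or 3 skeletal muscle markers (-0.18 against a positive test, 0.989), by either adjustment.

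In all, edgeR called 3360 of 13504 genes in DBA (24.9%), with 1501 higher and 1859 lower, and 194 higher and 118 lower by at least 2-fold; 5375 genes had an unadjusted p under 0.05. With library totals in place of TMM, 3105 were higher and 821 lower, a share of higher calls of 79.1% against 44.7%, and the median log2 fold change of all genes moved by 0.160. Under that scaling the medians of T and NK cell markers (-0.16 to -0.00), hypoxia genes (-0.11 to 0.05), clock genes (-0.15 to 0.01) and immediate early genes (-0.04 to 0.13) moved to or across 0. The oxidative phosphorylation median moved to -0.02 with 4 genes higher and 9 lower, while matrix genes kept 39 higher and 0 lower. The count was 950 without the shallow libraries, 868 with the GC offset as well and 1648 when only the DBA groups were fitted. It was 5091 without DBA control 2, 1318 without DBA control 3, 2235 without DBA ligated 1, 1811 without S41 and 1793 without S42.

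In C57 mice, natriuretic peptides and several fetal contractile and matrix genes rose after ligation, and several fat-burning genes fell. Nppa was at 647 ± 189.9 CPM after ligation against 131 ± 21.1 in controls and Acta1 at 1303 ± 610.2 against 193 ± 26.6. Myh7 was at 1401 ± 906 (2759.8 in ligated 1, 915 to 969 in others) against 428 ± 71.1. Postn was at 332 ± 194 against 61.9 ± 6.61. Their log2 fold changes were 2.30 ± 0.26, 2.75 ± 0.32, 1.71 ± 0.29 and 2.42 ± 0.34 (edgeR adjusted p = 0.000276, 0.000276, 0.00243 and 0.000522). Col1a1 rose from 177 ± 17.4 to 523 ± 213 CPM (1.56 ± 0.21) and Col3a1 from 518 ± 37.0 to 1414 ± 519 (1.45 ± 0.20), with edgeR adjusted p = 0.000403 for each. Timp1 rose from 1.77 ± 0.201 to 10.8 ± 4.52 (2.59 ± 0.32) and Ankrd1 from 1539.6 ± 300.5 to 3660.0 ± 836 (1.25 ± 0.21), with edgeR adjusted p = 0.000298 and 0.00228. Nppb was at 245 ± 48.2 against 121 ± 33.7 CPM (1.01 ± 0.30) and Myh6 at 36759.6 ± 4209 against 48415 ± 2638 (-0.40 ± 0.12), with edgeR adjusted p = 0.0336 and 0.0338. Over the alternatives, Nppb ran from 0.010 to 0.0902 and Myh6 from 0.00581 to 0.157 in edgeR adjusted p. Nppb was not called without C57 control 1 (0.0628), 3 (0.0822) or 4 (0.0818), C57 ligated 1 (0.0863), 3 (0.0533) or 4 (0.0740) or the shallow libraries (0.0902), and Myh6 not without C57 control 1 (0.0939), 2 (0.0720) or 3 (0.0569) or C57 ligated 1 (0.10) or 3 (0.111), by the same edgeR test.

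The largest rises in C57 hearts included secreted and matrix genes. Cthrc1, a secreted collagen-modifying protein, had 3 counts over the 4 controls and 2.08 CPM after ligation, a ratio of 30.7 with a counting interval of 10.5 to 149, and of 19.4 without C57 ligated 1 (edgeR adjusted p = 0.00415). The microfibril protein Ltbp2 rose from 3.53 ± 0.985 to 35.8 ± 21.1 CPM (3.37 ± 0.39, edgeR adjusted p = 0.000276). The cartilage intermediate layer protein Cilp rose from 13.5 ± 1.05 to 106 ± 55.7 (2.97 ± 0.29, edgeR adjusted p = 0.000124). Dio2, the enzyme that activates thyroid hormone, rose from 3.15 ± 1.70 to 19.5 ± 11.9 (2.73 ± 0.44, edgeR adjusted p = 0.00145). The basement membrane protein Frem1 rose by 2.77 ± 0.54 and Col9a2 by 2.69 ± 0.56 (edgeR adjusted p = 0.00443 and 0.00659; 1.98 and 1.94 without C57 ligated 1), and Acta1 was also among the largest rises. The largest falls were in Angptl4, an inhibitor of lipoprotein lipase, at -2.41 ± 0.64, Ifltd1 at -2.18 ± 0.45 and Pdk4, the kinase that restrains pyruvate oxidation, at -1.99 ± 0.47 (edgeR adjusted p = 0.0211, 0.0106 and 0.0117). The Wnt-binding Sfrp5 was at -1.77 ± 0.37, the potassium channel subunit Kcnv2 at -1.76 ± 0.31 and the enkephalin precursor Penk at -1.71 ± 0.35 (edgeR adjusted p = 0.00658, 0.00279 and 0.00598). The mitochondrial uncoupling protein Ucp3 was at -1.67 ± 0.34 and the thioesterase Acot1, which has close copies, at -1.63 ± 0.29 (edgeR adjusted p = 0.00560 and 0.00280). Pdk4 was at 1776 ± 1274 CPM in controls and 447 ± 88.1 after ligation. Over the alternatives the edgeR adjusted p ran from 0.00606 to 0.133 for Angptl4, from 0.00390 to 0.0921 for Pdk4 and from 0.000244 to 0.0711 for Ifltd1. Angptl4 was not called without C57 control 1 (-1.58, edgeR adjusted p = 0.103), C57 ligated 1 (0.0847) or 3 (0.0585) or the shallow libraries (0.133), and Pdk4 not without C57 control 1 (-1.35, edgeR adjusted p = 0.0525) or the shallow libraries (0.0782), by the same edgeR test.

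Among the lists, 44 of 47 matrix genes were higher in C57 after ligation and 0 lower, 45 and 0 adjusted over the list alone. Their median was 1.52 (camera adjusted p = 2.85e-35; adjusted p = 0.12 with an estimated correlation). The fibrillin gene Fbn1 rose by 1.68 ± 0.20 and Col8a1 by 2.10 ± 0.25 (edgeR adjusted p = 0.000276 for each). Of 19 stress genes 12 were higher and 0 lower, 13 and 0 adjusted over the list alone. Their median was 0.61 (camera adjusted p = 1.95e-08; adjusted p = 0.12 with an estimated correlation). They included the actin crosslinker Actn1 at 0.68 ± 0.11 (edgeR adjusted p = 0.00115). Of 24 TGF-beta genes 10 were higher and 0 lower, 13 and 0 adjusted over the list alone. Their median was 0.48 (camera adjusted p = 7.12e-06; adjusted p = 0.12 with an estimated correlation). They included Tgfb3 at 0.69 ± 0.10 and the transcription factor Meox1 at 1.26 ± 0.20 (edgeR adjusted p = 0.000805 and 0.00115). Of 16 fibroblast markers 5 were higher and 0 lower by either adjustment. Their median was 0.17 (camera adjusted p = 0.0105; adjusted p = 0.30 with an estimated correlation). They included Mfap5 at 1.78 ± 0.24 and Pi16 at 1.28 ± 0.18 (edgeR adjusted p = 0.000403 and 0.000432). Of 24 macrophage markers 11 were higher and 0 lower, 17 and 0 adjusted over the list alone. Their median was 0.63 (camera adjusted p = 2.35e-07; adjusted p = 0.12 with an estimated correlation). They included the receptor Trem2 at 1.91 ± 0.37 and Laptm5 at 0.64 ± 0.13 (edgeR adjusted p = 0.00460 and 0.00552). Of 16 complement genes 5 were higher and 0 lower, 8 and 0 adjusted over the list alone. Their median was 0.39 (camera adjusted p = 9.41e-05; adjusted p = 0.12 with an estimated correlation). They included C4b at 1.20 ± 0.22 (edgeR adjusted p = 0.00345).

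Cell cycle genes had 10 of 30 higher and 1 lower, 16 and 1 adjusted over the list alone. Their median was 0.82 (camera adjusted p = 2.65e-06; adjusted p = 0.35 with an estimated correlation). Cyclin B1, Ccnb1, rose by 2.41 ± 0.41 and the ribonucleotide reductase subunit Rrm2 by 1.74 ± 0.34, while the kinetochore gene Cenpf fell by 1.17 ± 0.25 (edgeR adjusted p = 0.00235, 0.00458 and 0.00683). Immediate early genes had 5 of 20 higher and 0 lower, 7 and 0 adjusted over the list alone. Their median was 0.67 (camera adjusted p = 3.68e-05; adjusted p = 0.30 with an estimated correlation). They included the transcription factors Egr3 at 2.06 ± 0.37 and Nr4a3 at 1.69 ± 0.40 (edgeR adjusted p = 0.00298 and 0.0115). Of 30 fatty acid oxidation genes 20 were lower and 0 higher, 25 and 0 adjusted over the list alone. Their median was -0.49 (camera adjusted p = 1.01e-14; adjusted p = 0.12 with an estimated correlation); Hadha, a subunit of the trifunctional protein, was at -0.63 ± 0.11 (edgeR adjusted p = 0.00292). Of 60 oxidative phosphorylation genes 13 were lower and 0 higher, 22 and 0 adjusted over the list alone. Their median was -0.19 (camera adjusted p = 2.35e-07; adjusted p = 0.30 with an estimated correlation). Of 30 calcium handling genes 9 were lower and 0 higher, 10 and 0 adjusted over the list alone. Their median was -0.17 (camera adjusted p = 0.00354; adjusted p = 0.30 with an estimated correlation). Of 20 sarcomere genes 5 were lower and 0 higher by either adjustment. Their median was -0.12 (camera adjusted p = 0.0103; adjusted p = 0.30 with an estimated correlation).

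Other list results in C57 were smaller. Endothelial markers had 2 of 16 higher and 0 lower, 5 and 0 adjusted over the list alone. Their median was 0.23 (camera adjusted p = 0.0250; adjusted p = 0.35 with an estimated correlation). Epicardial and mesothelial markers had 1 of 6 higher and 0 lower, 2 and 0 adjusted over the list alone. Their median was 1.91 (camera adjusted p = 0.0272; adjusted p = 0.36 with an estimated correlation). The gene called there is Msln, with 2 counts over the 4 controls and a ratio of 32.3 (counting interval 8.94 to 267; 11.1 without C57 ligated 4, edgeR adjusted p = 0.0661), and the list was not called without C57 control 4 (camera adjusted p = 0.0684), C57 ligated 4 (0.174) or the shallow libraries (0.0598), with the GC offset (0.0592), in the 12 numbered libraries with the replicate block (0.0630) or without (0.0897), or by fry (0.0542). Fry called neither of the next 2 lists. Interferon genes had 3 of 29 higher and 0 lower, with 0 adjusted over the list alone. Their median was 0.23 (camera adjusted p = 0.0135; adjusted p = 0.64 with an estimated correlation), and were not called without C57 control 2 (camera adjusted p = 0.172) or C57 ligated 3 (0.178). Adipocyte markers had 1 of 6 lower and 0 higher, 3 and 0 adjusted over the list alone. Their median was -1.14 (camera adjusted p = 0.0446; adjusted p = 0.35 with an estimated correlation), and were not called without C57 control 3 (camera adjusted p = 0.0633) or 4 (0.110) or C57 ligated 2 (0.235) or 3 (0.0507). The other 16 lists were not called by camera in C57, with the smallest adjusted p for pericyte markers (0.0687), with 4 higher and 1 lower, 5 and 1 adjusted over the list alone. The median and the mean or test differed in sign for glycolysis (0.04, with a negative test), glucocorticoid genes (0.16 and -0.21), clock genes (0.02 and -0.02) and skeletal muscle markers (-0.04 and 0.15).

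In all, edgeR called 1796 genes in C57 (13.3%), with 978 higher and 818 lower, and 267 higher and 55 lower by at least 2-fold; 4108 genes had an unadjusted p under 0.05. With library totals 1680 were higher and 426 lower, a share of higher calls of 79.8% against 54.5%, and the median of all genes shifted by 0.113. The medians of Schwann cell markers (-0.04 to 0.08), skeletal muscle markers (-0.04 to 0.08) and known strain genes (-0.05 to 0.06) changed sign. Matrix genes kept 44 higher and 0 lower under that scaling, and fatty acid oxidation 0 and 18. The count of called genes was 2829 without the shallow libraries, among them 42 matrix genes with a median of 1.49. It was 931 without C57 control 1, 886 without C57 control 2, 618 without C57 ligated 1, 754 without C57 ligated 3 and 2854 without DBA control 4, which shares the fit.

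Most genes called in either strain moved in the same direction in both. Between the strains, 583 genes were called higher in both and 509 lower in both, where independent lists of these lengths would share 109 and 113, and 2 genes were called in opposite directions. Of the 4062 genes called in either strain, 95.4% had fold changes of the same sign, against 77.9% of all genes. Across genes the fold changes had a Pearson correlation of 0.64 and a Spearman correlation of 0.70; genes are not independent replicates. The comparisons share no control library, but across genes the shift of DBA controls 3 and 4 had a Spearman correlation of 0.48 with the deviation of C57 control 1 and of -0.63 with the DBA fold changes. Without these shallow libraries the correlations of the responses were 0.57 (Pearson) and 0.63 (Spearman). The 1092 shared calls became 598 without the shallow libraries and 536 with the GC offset as well. In the overlap of the ligation response between the strains, the shared calls were 617 without DBA control 3, 683 without DBA ligated S41, 676 without S42, 581 without C57 control 1, 563 without C57 control 2, 436 without C57 ligated 1 and 521 without C57 ligated 3.

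The interaction test called no gene. In the panel Myh7 differed most, with C57 ligated 1 outlying. Its response was lower in DBA by -2.09 ± 0.41 (edgeR adjusted p = 0.387). Next were Timp1 (-1.73 ± 0.43, edgeR adjusted p = 0.526), Acta1 (-1.58 ± 0.42, 0.587) and Postn (-1.28 ± 0.46, 0.802). Nppa (-0.86 ± 0.34), Col1a1 (-0.66 ± 0.29), Ankrd1 (-0.61 ± 0.30), Col3a1 (-0.49 ± 0.28), Myh6 (-0.30 ± 0.17) and Nppb (0.23 ± 0.42) had edgeR adjusted p from 0.831 to 0.922. By edgeR 0 of 13504 genes were called, with 782 at an unadjusted p under 0.05; voom called 0 with 719, and DESeq2 called 16, of which 3 were positive and 13 negative, with 884. DESeq2's calls included Myh7 (adjusted p = 0.0453) and Timp1 (adjusted p = 0.0441); over all alternatives the adjusted p of these genes ran from 0.0453 to 0.762 and from 0.0441 to 0.987.

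Collagens and matrix genes rose less in DBA than in C57, as a list. Their median difference was -0.58 (camera adjusted p = 1.81e-11; adjusted p = 0.75 with an estimated correlation), with 0 genes called over all genes. Adjusted over the list alone 13 were negative and 0 positive, namely Ltbp2, Timp1, Cilp, Col12a1, Lox, Mfap4, Col8a1, Fbn1, Thbs4, Cthrc1, Vcan, Postn and Eln. Immediate early genes had a median of -0.65 (camera adjusted p = 4.68e-07; adjusted p = 0.75 with an estimated correlation), with 6 negative adjusted over the list alone, Egr1, Egr3, Nr4a1, Nr4a3, Fos and Egr2. Stress genes had a median of -0.29 (camera adjusted p = 0.00253; adjusted p = 0.75 with an estimated correlation), with Myh7 and Acta1. Fatty acid oxidation (0.20, camera adjusted p = 0.0190; adjusted p = 0.75 with an estimated correlation) and interferon genes (0.26, camera adjusted p = 0.0283; adjusted p = 0.78 with an estimated correlation) had positive medians. Macrophage markers had a negative one (-0.18, camera adjusted p = 0.0497; adjusted p = 0.75 with an estimated correlation). These 3 lists had no gene adjusted over the list alone, and by fry none of the 6 lists was called, with adjusted p from 0.597 to 0.729. Of the other 26 lists, none was called by camera, but TGF-beta, endothelial and calcium handling genes were with the GC offset (0.0201, 0.0420 and 0.0115). Leaving out 1 library added calls of TGF-beta (4 libraries, down to 0.00315), B cell (4, 0.0198), endothelial (3, 0.0435), known strain (3, 0.0184), calcium handling (2, 0.00499), clock (2, 0.0252), oxidative phosphorylation (1, 0.0155) and glycolysis genes (1, 0.0371). Of the 26, adjusted over the list alone only the clock list had a gene, 1 negative. The immediate early call ended with the GC offset and without the shallow libraries (0.0549 by camera). Without DBA control 2 the camera adjusted p was 0.0769 for stress genes, 0.0502 for fatty acid oxidation, 0.168 for interferon and 0.240 for macrophages; without C57 control 1 it was 0.103, 0.275 and 0.0548 for the last 3. The fatty acid oxidation call also ended without DBA control 1 (0.118), DBA ligated S40 (0.103) or C57 ligated 1 (0.182) or 3 (0.0859), and the interferon call without DBA control 1 (0.198), DBA ligated S42 (0.172) or C57 control 4 (0.0752) or C57 ligated 4 (0.427), by camera. The macrophage call ended without DBA control 1 (0.0638), DBA ligated S40 (0.0605) or S42 (0.114), C57 control 2 (0.0562) or 4 (0.0558), or C57 ligated 1 (0.131) or 3 (0.247), by camera.

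**Figure D3:**
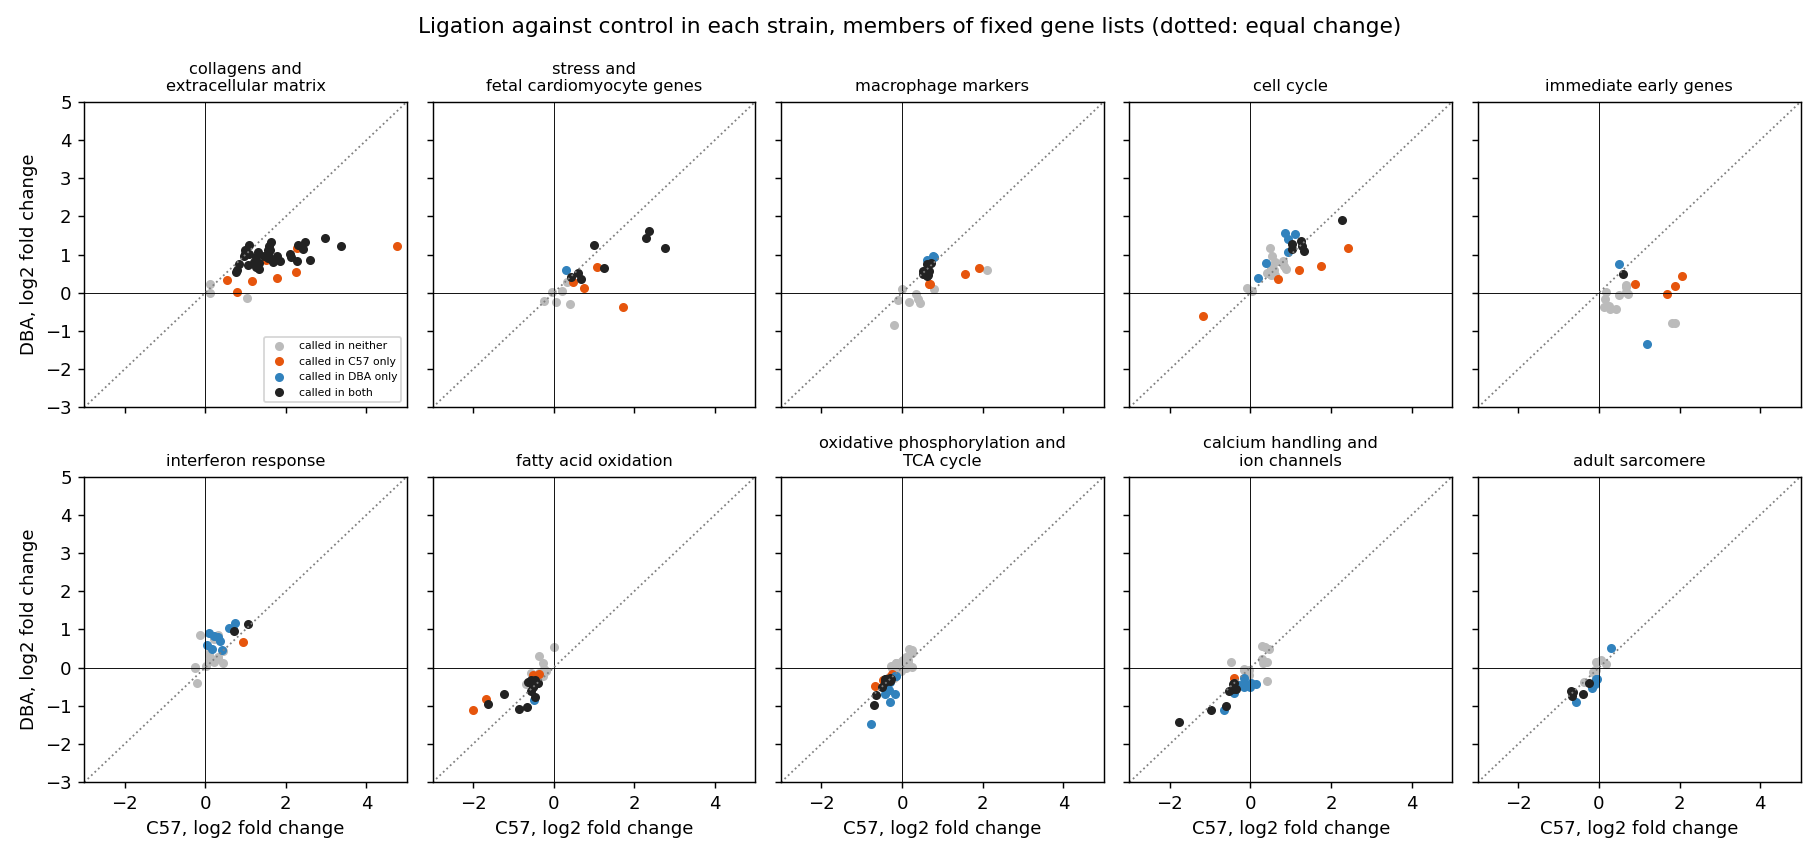
Log2 fold changes after ligation in C57 (x axis) and DBA (y axis) of the tested genes of 10 lists, 1 panel per list; each point is a gene, colours show whether it was called in neither strain, in 1 or in both, and the dotted line marks an equal change. Matrix genes have a median of 1.52 in C57 and 0.90 in DBA.

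Without ligation, DBA hearts differed from C57 hearts in single inflammatory, contractile and metabolic genes. The macrophage markers Spp1, which encodes osteopontin, and the galectin Lgals3 differed by 7.88 ± 0.66 and 3.73 ± 0.34 (edgeR adjusted p = 1.5e-07 and 4.3e-07), and the chemokine Cxcl16 by 1.69 ± 0.17 (edgeR adjusted p = 1.7e-06). Acta1 was at 1539 ± 663 CPM in DBA controls against 193 ± 26.6 in C57 controls and Myh7 at 2609 ± 693 against 428 ± 71.1, differences of 2.99 ± 0.32 and 2.61 ± 0.30 (edgeR adjusted p = 2.5e-06 and 7.4e-06). The cardiac actin gene Actc1 was lower in DBA by -1.33 ± 0.15 and Mlycd, an enzyme of malonyl-CoA breakdown, by -1.32 ± 0.14 (edgeR adjusted p = 4.8e-06 and 3.3e-06). None of these genes lost its call under any alternative.

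The largest differences between control hearts were of genes read almost only in 1 strain. Hamp2, a hepcidin gene with a near-identical copy, was at 60.2 ± 27 CPM in DBA with 1 count in the 4 C57 controls, a ratio of 2659.9 (counting interval 477 to 105059.9). Ifi202b, of an interferon-inducible family with close copies, had a ratio of 1014 (182 to 40036). Mrap2, a melanocortin receptor accessory protein, was at least 191-fold higher in DBA at 13 ± 5.83 CPM, and the mast cell protease Mcpt2 at least 99.7-fold. The collagen prolyl hydroxylase subunit P4ha3 was at least 89.7-fold higher (6.10 ± 7.43 CPM), but 35.6-fold without DBA control 4, the complement proteases C1s2 and C1rb at least 67.5-fold and 59.7-fold and the MHC gene H2-Q1 at least 49.7-fold. Lower in DBA were the olfactory receptor gene Olfr1033, at least 152-fold against 10.5 ± 1.15 CPM in C57, Ifltd1 at least 50.7-fold and the natural killer receptor gene Klra9 at least 34.0-fold. Trim12a had 1 count in DBA (ratio 405, 72.7 to 16006), and the carbohydrate kinase Fggy and the substance P precursor Tac1 had 3 each (77.7, 26.6 to 377, and 34.1, 11.7 to 165). Nxpe4 was at 0.279 against 14.9 ± 2.44 CPM (-6.08 ± 0.29) and Trim30d at 0.0991 against 4.02 CPM (-5.29 ± 0.50), with edgeR adjusted p = 8.77e-11 and 7.00e-07. Mcpt2, C1s2, C1rb, H2-Q1, Olfr1033, Klra9, Trim12a and Trim30d belong to families with similar copies between which reads can be split, so their values are uncertain.

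Of the 12 tested known strain genes, 6 were called, 3 in each direction, in controls and after ligation. Known directions were not compared. Adjusted over the list alone there were 3 and 3 in controls and 4 higher and 3 lower after ligation. The cardiac kinase Tnni3k was at 37.2 ± 4.72 CPM in DBA against 173 ± 7.47 in C57 controls, a difference of -2.20 in controls and -1.84 after ligation (edgeR adjusted p = 1.31e-11 and 5.27e-11). The mitochondrial transhydrogenase Nnt differed by -1.06 and -0.85 (edgeR adjusted p = 9.55e-06 and 8.38e-05) and Cox7a2l, a factor of respiratory supercomplexes, by -1.30 and -0.99 (7.10e-07 and 1.15e-05). The glyoxalase Glo1 was higher in DBA by 0.86 and 1.01 (edgeR adjusted p = 3.80e-07 and 3.47e-08), the heme enzyme Alad by 1.63 and 1.72 (3.18e-06 and 1.10e-06). The MHC gene H2-Ea, counted under the symbol H2-Ea-ps, had a ratio of 524 in controls (145 to 4324) and was at least 556-fold higher in DBA after ligation. Genes not called by edgeR in controls and after ligation included Gpnmb (0.84 and 0.70, edgeR adjusted p = 0.182 and 0.232), Ltbp4 (-0.13 and -0.15, 0.645 and 0.648), Ahr (-0.12 and -0.16, 0.577 and 0.445), Abcb10 (-0.19 and -0.14, 0.322 and 0.521) and Wdfy1 (0.01 and 0.18, 0.973 and 0.0879). In controls Gpnmb was called without DBA control 1 (edgeR adjusted p = 0.0112) and Abcb10 without DBA control 2 (0.0372).

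The cytokine and chemokine list kept its call with an estimated correlation. In controls 15 of 21 genes were higher in DBA and 0 lower, 17 and 0 adjusted over the list alone. Their median was 1.69 (camera adjusted p = 1.13e-08; adjusted p = 0.022 with an estimated correlation). They included the interleukin-1 antagonist Il1rn at 4.90 ± 0.62 and Ccl2 at 2.26 ± 0.33 (edgeR adjusted p = 1.8e-05 and 7.7e-05). Of 47 matrix genes 34 were higher and 0 lower, 38 and 0 adjusted over the list alone. Their median was 0.85 (camera adjusted p = 4.29e-11; adjusted p = 0.43 with an estimated correlation). They included Mfap4 at 1.75 ± 0.23 and Col14a1 at 1.17 ± 0.17 (edgeR adjusted p = 3.0e-05 and 8.7e-05); without the shallow libraries 17 were higher and 0 lower. Macrophage markers had 12 higher and 2 lower of 24, 14 and 2 adjusted over the list alone. Their median was 0.68 (camera adjusted p = 0.000413; adjusted p = 0.40 with an estimated correlation). Complement genes had 8 higher and 0 lower of 16 by either adjustment. Their median was 0.50 (camera adjusted p = 0.00135; adjusted p = 0.40 with an estimated correlation). TGF-beta genes had 12 higher and 1 lower of 24, 13 and 1 adjusted over the list alone. Their median was 0.37 (camera adjusted p = 0.00638; adjusted p = 0.41 with an estimated correlation). Fibroblast markers had 8 higher and 1 lower of 16, 10 and 2 adjusted over the list alone. Their median was 0.33 (camera adjusted p = 0.0119; adjusted p = 0.40 with an estimated correlation). C4b differed by 2.15 ± 0.22, the smooth muscle actin Acta2 by 1.98 ± 0.23 and the fibroblast marker Dpt by 1.01 ± 0.12 (edgeR adjusted p = 2.0e-06, 6.0e-06 and 5.6e-06). Stress genes had 11 higher and 2 lower of 19, 11 and 5 adjusted over the list alone (0.66, camera adjusted p = 0.0188; adjusted p = 0.43 with an estimated correlation).

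Oxidative phosphorylation was lower as a list in DBA controls, with 1 gene higher and 18 lower of 60, 2 and 24 adjusted over the list alone. Their median was -0.20 (camera adjusted p = 0.000151; adjusted p = 0.47 with an estimated correlation). Sarcomere genes had 1 higher and 9 lower of 20, 2 and 9 adjusted over the list alone. Their median was -0.23 (camera adjusted p = 0.00750; adjusted p = 0.40 with an estimated correlation). Fatty acid oxidation had 0 higher and 8 lower of 30 by either adjustment, with a median of -0.19 (camera adjusted p = 0.00899; adjusted p = 0.56 with an estimated correlation). Endothelial markers had 0 higher and 5 lower of 16, 0 and 8 adjusted over the list alone. Their median was -0.22 (camera adjusted p = 0.00700; adjusted p = 0.41 with an estimated correlation). Erythroid markers had 0 higher and 3 lower of 3 by either adjustment, with a median of -1.44 (camera adjusted p = 0.0177; adjusted p = 0.40 with an estimated correlation). Interferon genes had 1 higher and 7 lower of 29, 1 and 10 adjusted over the list alone. Their median was -0.35 (camera adjusted p = 0.0119; adjusted p = 0.60 with an estimated correlation). In that list Rsad2 was at -1.63 ± 0.20 but Xaf1 at 2.52 ± 0.18 (edgeR adjusted p = 1.4e-05 and 1.7e-08). Immediate early genes had 5 higher and 1 lower of 20, 6 and 1 adjusted over the list alone (0.43, camera adjusted p = 0.0213; adjusted p = 0.56 with an estimated correlation). Without DBA control 2 the camera adjusted p was 0.0761 for stress genes, 0.0542 for fibroblast markers and 0.0527 each for the erythroid, sarcomere, interferon and immediate early lists. Without DBA control 4 it was 0.150 for immediate early genes, without DBA control 1 0.0567 for interferon genes, and without C57 control 1 0.0518 for stress, 0.0682 for interferon and 0.0906 for immediate early genes. Without the shallow libraries it was 0.114 for endothelial markers and 0.626 for immediate early genes by camera.

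The other 18 lists were not called between the control groups by camera, with the smallest adjusted p for glycolysis (0.0588), with 2 genes higher and 4 lower, 2 and 5 adjusted over the list alone. Signs differed between the median and the mean or test for calcium handling (median 0.04, mean -0.03), pericyte markers (-0.05 and 0.22), known strain genes (-0.06 and 0.60, with a negative test) and skeletal muscle markers (0.20, with a negative test).

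In all, 3035 genes differed between control hearts by edgeR (22.5%), 1696 higher and 1339 lower in DBA, and 657 higher and 301 lower by at least 2-fold; 4765 had an unadjusted p under 0.05. With library totals 2114 were higher and 961 lower, a share of higher calls of 68.7% against 55.9%, and the median of all genes shifted by 0.059. The medians of pericyte markers (-0.05 to 0.02) and known strain genes (-0.06 to 0.00) moved to or across 0. The count was 1612 when only the control groups were fitted.

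After ligation, DBA hearts again differed from C57 hearts in single inflammatory, contractile and matrix genes. Spp1 was higher by 6.37 ± 0.50, Cxcl16 by 1.47 ± 0.16, C4b by 2.17 ± 0.21 and Dpt by 1.08 ± 0.11 (edgeR adjusted p = 4.8e-08, 2.8e-06, 5.9e-07 and 2.0e-06), and Actc1 was lower by -1.41 ± 0.15 (edgeR adjusted p = 1.9e-06). Cilp, of the matrix list, was lower in DBA by -2.21 ± 0.27, while Mmp2 was higher by 0.78 ± 0.13 (edgeR adjusted p = 1.1e-05 and 0.00020). None of them lost its call under any alternative.

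The gene with the smallest p between ligated hearts was Lgr6, a receptor for R-spondins, at 5.27 ± 0.351 CPM in DBA and 38.0 ± 1.43 in C57 (-2.85 ± 0.10, edgeR adjusted p = 1.65e-12). The inward rectifier channel gene Kcnj14 was at 74.4 ± 2.73 and 1.86 ± 0.560 CPM (5.29 ± 0.20, edgeR adjusted p = 7.09e-12). Also higher in DBA were Pianp (3.84 ± 0.18), Iqgap2 (2.57 ± 0.12), the glycogen phosphorylase Pygl (2.10 ± 0.11), the smooth muscle light chain Myl9 (3.33 ± 0.18) and Serpina1b (6.34 ± 0.30), Serpina3h (7.38 ± 0.37) and Eno1b (4.65 ± 0.22), which have close copies (edgeR adjusted p from 4.76e-11 to 4.04e-10). Also lower in DBA were Nxpe4 (-5.12 ± 0.21), the securin Pttg1 (-3.94 ± 0.16), the actin regulator Cyfip2 (-3.23 ± 0.14), Rab6b (-4.31 ± 0.19), the calcium channel gene Cacna1h (-3.32 ± 0.15), Tceanc2 (-3.82 ± 0.17) and Mndal (-3.32 ± 0.15), which has close copies (edgeR adjusted p from 1.58e-11 to 4.76e-11). None of these 16 genes lost its call under any alternative.

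Of the lists, cytokines again kept their call with an estimated correlation, with 14 higher and 0 lower of 21 in ligated DBA hearts, 19 and 0 adjusted over the list alone. Their median was 1.07 (camera adjusted p = 3.92e-09; adjusted p = 0.016 with an estimated correlation). Fibroblast markers had 10 higher and 0 lower of 16 by either adjustment, with a median of 0.45 (camera adjusted p = 0.000322; adjusted p = 0.18 with an estimated correlation). Complement genes had 9 higher and 1 lower, 10 and 1 adjusted over the list alone. Their median was 0.61 (camera adjusted p = 0.00112; adjusted p = 0.24 with an estimated correlation). Macrophage markers had 10 higher and 2 lower, 11 and 2 adjusted over the list alone. Their median was 0.25 (camera adjusted p = 0.00417; adjusted p = 0.54 with an estimated correlation). Matrix genes had 10 higher and 1 lower by either adjustment, with a median of 0.23 (camera adjusted p = 0.00417; adjusted p = 0.82 with an estimated correlation, and 0.311 without C57 ligated 2). Sarcomere genes had 1 higher and 9 lower, 2 and 13 adjusted over the list alone. Their median was -0.30 (camera adjusted p = 0.000153; adjusted p = 0.15 with an estimated correlation). Oxidative phosphorylation had 1 higher and 8 lower, 1 and 6 adjusted over the list alone. Their median was -0.18 (camera adjusted p = 0.000322; adjusted p = 0.67 with an estimated correlation). Erythroid markers had 0 higher and 3 lower by either adjustment, with a median of -1.08 (camera adjusted p = 0.0249; adjusted p = 0.27 with an estimated correlation). Clock genes had 3 higher and 8 lower of 18, 4 and 10 adjusted over the list alone (-0.56, camera adjusted p = 0.0288; adjusted p = 0.24 with an estimated correlation). They included the output genes Dbp (-2.02 ± 0.34) and Hlf (-1.54 ± 0.25; edgeR adjusted p = 0.00032 and 0.00024). Clock genes also differed between libraries of 1 group: Arntl was at 24.3, 17.2, 4.43 and 3.53 CPM in C57 controls 1 to 4 and at 5.15, 3.79, 4.52 and 17.1 CPM in C57 ligated 1 to 4, and between 17.6 and 30.6 CPM in the DBA libraries. The other 23 lists were not called by camera, with the smallest adjusted p for TGF-beta genes (0.0759), with 5 higher and 1 lower, 10 and 1 adjusted over the list alone. The median and the mean or test differed in sign for pericyte markers (-0.08 and 0.15), MHC class II genes (-0.02 and 0.29), known strain genes (-0.07 and 0.92) and atrial markers (-0.17, with a positive test).

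**Figure D4:**
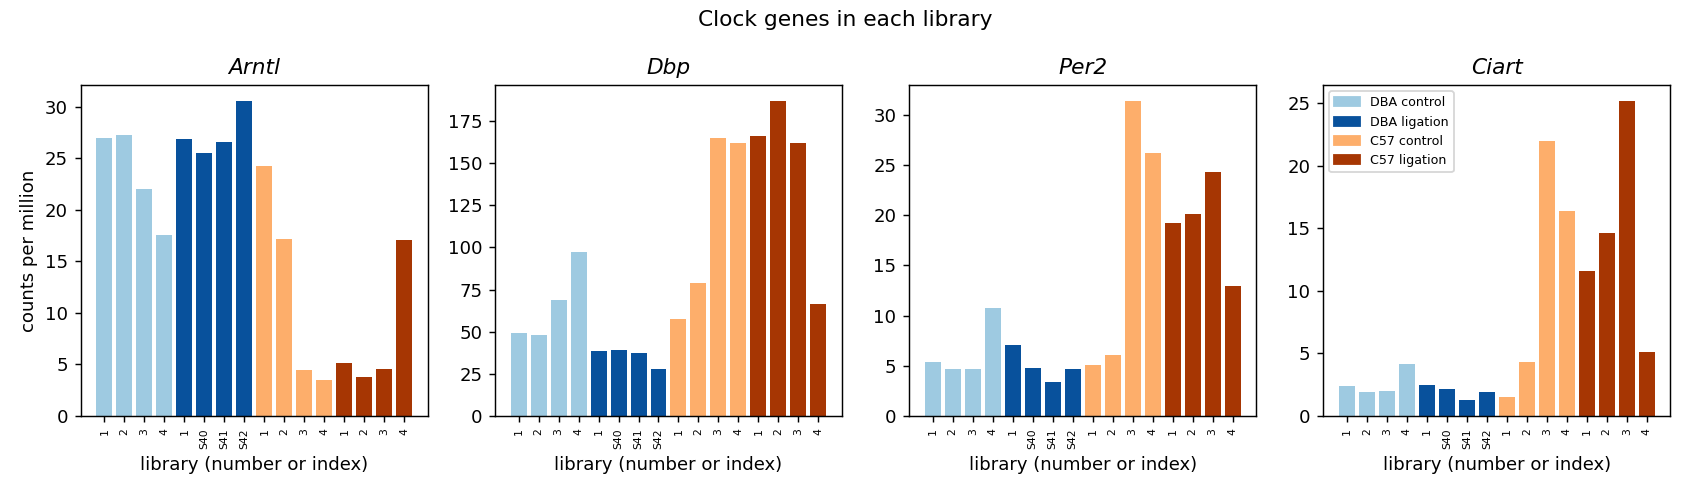
CPM of the clock genes Arntl, Dbp, Per2 and Ciart in each of the 16 libraries, as bars from 0 with 1 panel per gene and colours for the 4 groups. Dbp lies between 57.3 and 187 CPM in C57 and between 27.9 and 97.3 CPM in DBA.

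In all, 2624 genes differed between ligated hearts by edgeR (19.4%), 1434 higher and 1190 lower in DBA, and 540 higher and 311 lower by at least 2-fold; 4193 had an unadjusted p under 0.05. With library totals 2169 were higher and 764 lower, a share of higher calls of 74.0% against 54.6%, with a shift of the median by 0.106. List medians that moved to the other side of 0 under that scaling were those of endothelial (-0.07 to 0.03) and pericyte markers (-0.08 to 0.03), fatty acid oxidation (-0.07 to 0.04), glycolysis (-0.07 to 0.04), cell cycle (-0.04 to 0.06), interferon (-0.09 to 0.01), MHC class II (-0.02 to 0.09), unfolded protein response (-0.09 to 0.02) and known strain genes (-0.07 to 0.04). The count was 4162 when only the ligated groups were fitted and 4342 without the shallow libraries.

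The authors' deposited table lists 4008 genes at a false discovery rate under 0.05 for DBA injured against normal mice, with 1930 higher and 2078 lower. For C57 the authors' deposited table lists 2423, with 1345 higher and 1078 lower. Between the strains the authors' deposited table lists 3550 genes in normal and 3140 in injured mice. For the interaction, coded as the C57 minus the DBA response, the authors' deposited table lists 19 genes, 14 positive and 5 negative. Among them are Myh7 (log2 difference 2.09, false discovery rate 0.0027), Ltbp2 (2.11, 0.019), Timp1 (1.74, 0.034), Egr1 (2.54, 0.037) and Dio2 (2.52, 0.021) in the authors' deposited table; these 5 were chosen here after their values were seen. The authors' deposited table and the fold changes computed here correlated at 0.999 or more across genes in each comparison, and 3344, 1795, 3017 and 2621 genes were called in both sources for DBA ligation, C57 ligation, control strain and ligated strain.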

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

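The tests of the shallow libraries, of the GC offset on the number of calls, of the interaction as a strain difference, of single C57 controls, of the fibroblast share and of collection time were chosen only after the result was seen; the other splits, the shared controls and the other GC tests were chosen before.

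In 25 of 306 groups of 4 libraries over the 82 genes examined (8.2%), 1 library lay far from the other 3; chance gives about 1 in 20 groups of normal values (5.1% in simulated ones). Groups with 3 or fewer counts in total were left out after several had proved to be single counts. In C57 control 1 this held for Pdk4 (3684 CPM), Trim12a (11.9), Klra9 (4.02), Pttg1 (71.2) and Mndal (35.9), in C57 control 2 for Acta1 (233), and in C57 control 4 for Matn4 (0.431), Ltbp2 (2.07) and Nxpe4 (18.5). In DBA control 4 it held for P4ha3 (17.1), Pianp (26.5), Postn (290.3) and Tnni3k (30.1), in DBA control 2 for Lrrc10b (4.35) and Angptl4 (34.3) and in DBA control 3 for Camk1g (1.12). In the ligated groups it held for Myh7 in C57 ligated 1 (2759.8), Sln (2.87) and Myl7 (13.2) in C57 ligated 3, C1s2 (7.74) and Tnni3k (39.0) in DBA ligated 1, Sln (1.04), Mybphl (1.04) and Acot1 (5.13) in DBA ligated S40 and Tac1 (0.870) in DBA ligated S41.

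The responses of 6 lists differed between the strains by camera, and none by fry or with an estimated correlation. The camera adjusted p was 1.81e-11 for matrix, 4.68e-07 for immediate early, 0.00253 for stress, 0.0190 for fatty acid oxidation, 0.0283 for interferon and 0.0497 for macrophage genes.

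More genes were called after ligation in DBA than in C57, at a ratio of 1.87, which was 0.74 without DBA control 3, 0.81 without DBA control 4 and up to 5.05 without C57 ligated 1. With the GC offset the ratio was 1.41, from 0.58 to 3.51 when 1 library was left out, so the GC trend of single libraries may account for part of it and cannot be told apart. Without DBA controls 3 and 4, which are shallow, the ratio was 0.14, but it also fell under 1 without controls 1 and 3 (0.24) or 1 and 4 (0.39), and not without 2 and 3 (1.49), 2 and 4 (1.13) or 1 and 2 (1.97). The test had been set to count other pairs under 1 against the shallow libraries, a badly chosen bound because both such pairs hold 1 of them, and the explanation stays open. The interaction test, which bears on a strain difference in the response, called 0 genes by edgeR and voom and 16 by DESeq2, with 782 at an unadjusted p under 0.05 by edgeR, and leaves that difference open.

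The 47 matrix genes, of which 44 were called higher after ligation in C57, had a median of 0.85 between DBA and C57 controls, with 34 called higher (17 without the shallow libraries; adjusted p of the list = 0.43 by camera with an estimated correlation). With the GC offset the median was 0.80 with 38 genes called, which argues against the GC trend alone. The 13 fibroblast markers outside the list had a median of 0.23, 0.61 below the matrix genes (two-sided permutation test, p = 0.0027). Genes are not independent, so a larger share of fibroblasts stays open. Over each single C57 control the median was 0.87 to 0.89, and over the pair not used for C57 ligation 0.82 to 0.95 (C57 ligation at least 1.32), which argues against chance values of single C57 controls. Over all genes such chance cannot be told apart, since without a shared control the covariance of the fold changes was -0.025 to 0.058 over 6 splits, with 0.001 at most in simulated groups with no effect (0.052 and 0.025 with the same controls). A strain difference in resting matrix expression stays open as a hypothesis.

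Clock genes differed within groups. Over the 16 libraries, the deviations of 3 genes that peak with Arntl and 9 that peak with Dbp correlated at r = -0.92 (permutation p = 0.00065; Spearman -0.91, permutation p = 0.0013; r = -0.88 without the 2 farthest libraries). With the GC trend taken out r was -0.91, which argues against GC content. Unrecorded times of day at collection may explain the pattern and the clock list between ligated hearts. A biological cause was not tested.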

How the results depend on the processing

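The GC offset, the fits without the shallow libraries, both together and the unblocked fit of 12 libraries were tests chosen only after the results were seen. No called named gene or retested list changed direction under any alternative. Total counts stayed within 1.5-fold under relative log expression, library totals, both filters, voom and the GC offset alone. By direction they did not under library totals, with 3105 higher and 821 lower for DBA ligation, 1680 and 426 for C57 ligation and 2169 and 764 between ligated hearts. DESeq2 called 16 genes for the interaction. Fits with only the groups compared gave 1648 calls for DBA ligation, 2571 for C57 ligation, 1612 between controls and 4162 between ligated hearts. Without the shallow libraries the calls were 950 for DBA ligation, 2829 for C57 ligation, 1 for the interaction, 4342 between ligated hearts and 598 for the overlap of the ligation response between the strains; with the GC offset as well they were 868, 2 for the interaction, 4309 and 536. Camera with an estimated correlation called 0, 0, 0, 1 and 1 lists for DBA ligation, C57 ligation, the interaction, controls and ligated hearts. Fry called 15, 14, 0, 16 and 13. Leaving out 1 library gave 1318 to 5091 calls for DBA ligation, 618 to 1869 among C57 libraries for C57 ligation, 2234 to 4031 between controls, 2051 to 2406 between ligated hearts, 436 to 1556 for the overlap and 0 for the interaction by edgeR, where 782 genes had an unadjusted p under 0.05. The lists called were then 2 to 9 for the interaction and 9 to 16 between controls. For the named genes, leaving out each library of the groups compared ended 95 calls, added 11 and left 1028 as they were in DBA, against 137, 20 and 947 in C57.

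With the replicate number as a block in the 12 numbered libraries, 343 genes were called for C57 ligation against 916 unblocked, and 1792 between controls. Libraries with the same number did not deviate together (correlations from -0.26 to 0.12), so the numbers do not pair them. No paired analysis was possible for results with the DBA ligated group, where 3 columns carry numbers that differ from the labels. Alternatives for normalized values were not run, since the values used are counts. In simulated data the interaction test recovered 11.9% of 1.5-fold, 52.2% of 2-fold and 97.0% of 4-fold differences.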

Other observations

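The windows of 20 genes were tests chosen only after the result was seen; the neighbour test and the other splits were chosen before.

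Genes next to each other on a chromosome were called together between the strains. In the comparison of controls, 16.8% of called genes were followed by a gene called in the same direction, against 11.4% on average and 13% at most in 1000 random reorderings. Linked strain variants may contribute, but DBA ligation, which compares mice of 1 strain, also gave 16.6% against at most 14.3%, so same-direction neighbours have other sources than linkage there, while C57 ligation gave 7.54% against at most 8.94%. Counted in any direction, the 26.1% of DBA ligation lay within the reorderings (26.6% at most), unlike the 27.5% between controls (24.5% at most). Among windows of 20 genes, a window over the protocadherin beta and gamma clusters on chromosome 18 (37400855 to 37841872), whose members have similar copies, held 12 genes called in controls and after ligation, 11 of them higher in DBA.

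Other splits of the same libraries bear on the counts of calls. For DBA ligation the real split gave 3360 calls and the highest other split 1, for C57 ligation 1796 and 3, and between ligated hearts 2624 and 0. In each of these only 1 of 35 splits, the real one, gave as many, the smallest share possible. Between controls the real split gave 3035, again 1 of 35, and the highest other 2474. It swaps DBA control 2 and C57 control 1, so the shallow libraries share a group. Why it gave 2474 was not tested. For the interaction the real split gave 0 calls, which each of the 100 splits drawn (5 calls at most) reaches by construction, so the splits decide nothing there.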
